A study of Mus musculus with 6 samples.

How the data were processed

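Renal tissue of 3 Dkk3 knockout mice and 3 C57Bl/6 mice was sequenced 7 days after unilateral ureteral obstruction, from 1 µg of RNA a sample, as single reads of 50 nt on an Illumina HiSeq instrument, in pools of 10 run on 3 lanes, per the labels. The submitters' processing notes name the mm10 build and edgeR, with no version. The aligner, the counting tool, the handling of strand and of reads with several matches, and the filter on low genes are not given in the sources used here.

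The files used here hold the authors' test results and no value per sample. Per the file headers, the deposited table gives for each of 18421 genes a log2 fold change, an average log2 CPM over all libraries, a likelihood-ratio score, a p-value and an FDR. The other deposited sheets list 74 Wnt-related, 20 Th1-related and 15 Th2-related genes, whose rows equal those of the main table, and a Gene Ontology table with gene numbers and p-values per term. The p-value of the authors equalled that of the likelihood-ratio score on a chi-square distribution with 1 degree of freedom within a relative 0.0001 for all 18421 genes, and the FDR of the authors equalled the Benjamini-Hochberg value over the whole table. The direction of the log2 fold change is not named in the header of the deposited table. The deleted gene is negative, so values were read as knockout over wild type. Library depth per sample is unknown, and no interval that needs it was computed.

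The plan made before the data were examined was a quasi-likelihood fit of counts, with the authors' own test in its place where no value per sample was at hand, and that second course was taken. A gene was called at an adjusted p under 0.05 in the authors' table. The standard error of a log2 fold change was approximated by its size divided by the square root of the likelihood-ratio score. Its median was 0.27 for genes at 1 to 10 CPM, 0.13 at 10 to 100 CPM and 0.13 at 100 CPM or more. Gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3, on the square root of the score with the sign of the fold change, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 34 lists of pathways and cell type markers fixed beforehand. The authors' 3 sheets were adjusted as a family of their own, as were the lists made after the results were seen. A test with an estimated correlation needs values per sample and was not run. Members were also counted with p-values adjusted over the list alone. List symbols were matched on the GENCODE name of the Ensembl identifier or on the listed symbol, older symbols included.

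Positions were taken from the GENCODE vM21 annotation of GRCm38, the same assembly as mm10, by Ensembl identifier, which gave 18314 genes a position and left 107 without one. Shares of called genes were compared with two-sided Fisher's exact tests with conditional odds ratios and 95% intervals in scipy 1.17.1. Distances run from gene edge to gene edge. Means of marker lists were compared by permuting genes between lists 100000 times, two-sided, which treats genes as independent although they are not. Sequence shared between genes was counted as distinct stretches of 50 nt, the read length, in the annotated transcripts.

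The rule for named genes, fixed beforehand, was Dkk3, then the 12 largest positive and 12 largest negative log2 fold changes among genes past an adjusted p of 0.05 at an average of 5 CPM or more, up to 4 members with the smallest p of each list, and the 5 with the smallest p of each authors' sheet. Col1a1 was named after its value was seen, as were members of the lists made later. Single values of some genes that the rule picks are not reported here, and the counts and tests of their lists include them. On simulated statistics for the 18421 genes, the list test found 96.7% of shifted lists in the right direction over 50 draws and called 0.333% of the others. Of genes shifted by 3 and by 6 standard errors, 29.9% and 99.7% were found over 20 draws, and 4.43% of calls were false. The simulated statistics were independent between genes, so these rates do not cover lists whose members vary together or the spread between mice.

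The alternatives were a threshold of 0.1, a fold change of at least 1.5, an average of at least 1 CPM, windows of 5 and 20 Mb about Dkk3 and, chosen after seeing the data, leaving out chromosome 7, dividing the scores by their inflation factor of 1.09 (median over genes at 1 CPM or more against the chi-square median), an F distribution with 14 degrees of freedom (4 residual and an assumed 10 prior), centring on the median, ranks or a correlation of 0.05 in cameraPR, and a threshold of 0.01 for Gene Ontology terms. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used.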

Results

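Transcript levels were compared in renal tissue of 3 Dkk3 knockout mice and 3 C57Bl/6 wild-type mice, 6 samples in all, taken 7 days after unilateral ureteral obstruction. This operation ties off 1 ureter, so that urine backs up into the kidney and the tubules atrophy while the interstitium fills with leukocytes and matrix. Dkk3 encodes a secreted glycoprotein of the dickkopf family, whose other members include antagonists of Wnt signalling. The comparison asked how loss of Dkk3 alters gene expression in the obstructed kidney, and separate gene sheets point to Wnt signalling and to Th1 and Th2 cells as the pathways of interest. Unobstructed kidneys were not analysed here. The genetic background and backcrossing of the knockout line are not given in the labels. Effects of background or colony therefore cannot be told apart from those of Dkk3 loss here. The values used were the authors' own test results for 18421 genes, with no value per sample, so the depth of each library and the spread between single mice are unknown.

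Dkk3 itself fell by 4.43 on the log2 scale in the knockout in the authors' deposited table, a 21.6-fold lower level, with an adjusted p of 2.98e-67 and an approximate standard error of 0.25. The gene (ENSMUSG00000030772) lies on the minus strand of chromosome 7 at 112116017 to 112159057 (GRCm38), and its annotated transcript has 8 exons. Its average over both genotypes was 23.2 CPM in the authors' deposited table. The table does not show which exons the remaining reads came from, and the labels could not be checked library by library.

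A total of 379 genes passed an adjusted p of 0.05 in the authors' deposited table, of which 215 were higher and 164 lower in the knockout. A fold change of 2 or more was reached by 117 of the higher and 80 of the lower genes. The largest increases among genes at 5 CPM or more were of antibody genes of plasma cells. In the authors' deposited table the joining chain gene Igj (Jchain) rose by 4.69 on the log2 scale (adjusted p = 2.00e-31). The gene listed as Igh-VJ558, which is the immunoglobulin alpha constant gene Igha by its Ensembl identifier, rose by 4.52 (adjusted p = 1.37e-18) in the authors' deposited table. Also higher in the authors' deposited table were Hddc3 (log2 fold change 1.86), Cd300lh (1.71), the microtubule-binding ubiquitin ligase gene Mid1 (1.69), and the p53-induced receptor gene Eda2r (1.67). Further increases in the authors' deposited table were of the TEAD transcription factor gene Tead2 (1.52), the microfibril gene Fbn2 (1.48), Cpt1c (1.46), the antisense gene Gm11747 (1.38), Xlr3b (1.37) and Cyp4a12b (1.30). The largest decreases among genes at 5 CPM or more in the authors' deposited table, besides Dkk3, were of Trim12a (log2 fold change -5.51), the ferritin light chain gene Ftl1 (-4.78), its relative Ftl1-ps1, a pseudogene by name but annotated as protein-coding and listed as LOC100862446 (-5.82), and Htatip2 (-3.96). Next among these genes in the authors' deposited table came Cyp4a14 (-3.14), Gas2 (-2.33), the uroplakin gene Upk1a (-2.16), Smim6 (-1.99) and the tissue kallikreins Klk1b5 (-1.97), Klk1 (-1.92) and Klk1b11 (-1.76). Ftl1 and Ftl1-ps1 have 675 stretches of 50 nt in common, 47.3% of those in Ftl1. Of the stretches in Ftl1, 446 (31.3%) also occur in other genes. The levels of Ftl1 and Ftl1-ps1, separate or together, are therefore uncertain. Members of the Klk1, Trim, Cyp4a and Xlr families may share reads too, which was not measured, and the level of antisense Gm11747 is open because the use of strand was not stated. The count fell to 81 with an F distribution of 14 degrees of freedom, 4 residual from 3 mice a group and 10 assumed as prior, so it depends on that assumption.

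**Figure D1:**
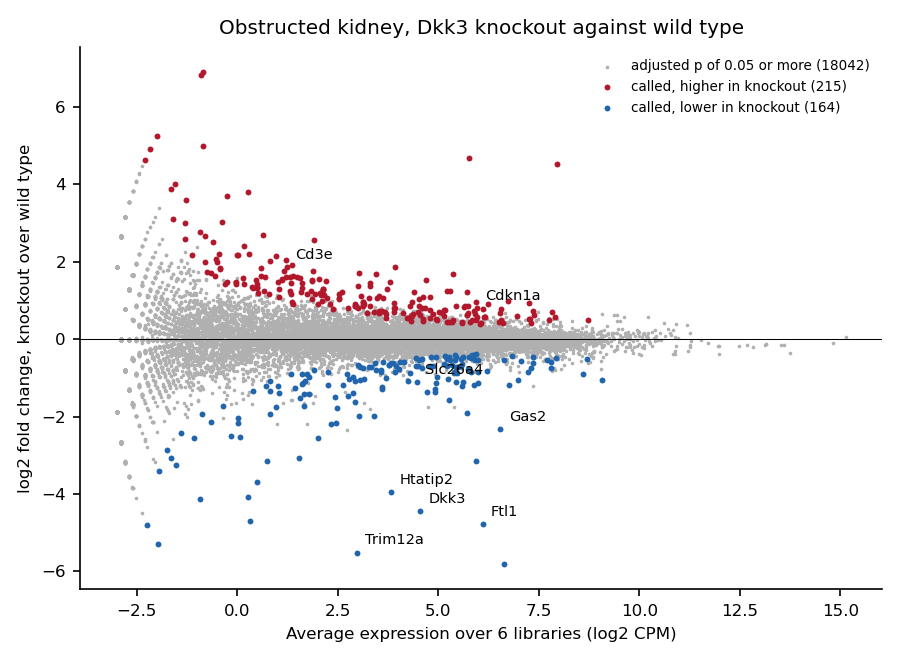
Log2 fold change of each of 18421 genes, knockout over wild type (vertical axis), against its average log2 CPM over the 6 libraries (horizontal axis), from the authors' deposited table. Red points are the 215 genes called higher and blue points the 164 called lower at an adjusted p of 0.05, and Dkk3 lies at -4.43.

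T cell markers rose together in the knockout. All 18 markers were above 0, and 13 passed the threshold over all genes and 17 when adjusted over the list alone. Their median log2 fold change was 1.46, or 2.76-fold (limma's cameraPR, adjusted p = 3.08e-26). Like every cameraPR p given here, this one rests on a preset correlation between genes and does not measure the spread between mice. Members of a list can vary together from mouse to mouse, and whether each knockout mouse shared a list's shift could not be checked. In the authors' deposited table the CD3 chains of the T cell receptor complex rose by 1.87 (Cd3e), 1.57 (Cd3g) and 1.52 (Cd3d) on the log2 scale, and the interleukin 7 receptor gene Il7r by 1.77, with the largest of the 4 adjusted p at 7.11e-04. These were scarce transcripts, with Cd3e at an average of 2.34 CPM in the authors' deposited table. With the F distribution 2 of the 18 markers still passed.

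The B cell and cytotoxic lists rose as well. Among 9 measured B cell and plasma cell markers, 2 rose, Igj and the plasma cell chaperone gene Mzb1 (log2 fold change 2.05, adjusted p = 7.87e-07 in the authors' deposited table), 3 rose when adjusted over the list alone, and the median was 0.77 (cameraPR adjusted p = 3.54e-09). The mature B cell gene Cd22 (0.85) did not pass, with an adjusted p of 0.234 in the authors' deposited table. Of 10 natural killer and cytotoxic markers 1 rose, the granzyme gene Gzmk (2.19, adjusted p = 5.23e-04 in the authors' deposited table), and 2 when adjusted over the list alone, with a list median of 0.62 (cameraPR adjusted p = 0.00223). The Th1 list, the cytokine programme of interferon-gamma producing helper cells, rose with a median of 0.27 (cameraPR adjusted p = 1.01e-05). Its 4 called members of 19 in the authors' deposited table were the chemokine gene Cxcl9 (1.12), its receptor gene Cxcr3 (1.29), Stat4 (1.16) and the interleukin 12 subunit gene Il12b (1.72), and 5 passed when adjusted over the list alone, while none was called with the F distribution. Il12b averaged 0.629 CPM in the authors' deposited table. At 1 CPM or more 3 Th1 members were called, as with the inflation factor. The Th2 list did not pass in the main setting (median 0.08, cameraPR adjusted p = 0.0593), but it did among genes at 1 CPM or more (cameraPR adjusted p = 0.0318) and without chromosome 7 (cameraPR adjusted p = 0.0399). Of its 17 measured members 2 rose in the authors' deposited table, the chemokine receptor genes Ccr4 (1.98) and Ccr8 (3.10), both under 1 CPM, and 5 higher and 1 lower member passed when adjusted over the list alone. Of these 2 calls 1 was left with the inflation factor and none with the F distribution or at 1 CPM or more, and Gzmk was not called with the F distribution either. Regulatory T and Th17 genes did not pass as a list (15 measured, cameraPR adjusted p = 0.127), though they did with ranks (cameraPR adjusted p = 0.0471). None of them was called in edgeR's test, 3 had an unadjusted p under 0.05, and 1 passed when adjusted over the list alone.

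Myeloid, interferon and antigen presentation lists rose as well. All 18 macrophage and dendritic cell markers were above 0 with a median of 0.48, a 1.40-fold difference (cameraPR adjusted p = 2.14e-09). None passed over all genes in edgeR's test, 12 had an unadjusted p under 0.05, and 12 passed when adjusted over the list alone. The integrin gene Itgax (0.74, adjusted p = 0.0906) and the complement gene C1qb (0.54, adjusted p = 0.0924) had the smallest p in the authors' deposited table. Interferon response genes rose as a list (20 measured, median 0.45, cameraPR adjusted p = 1.63e-13), with Igtp (0.45) and the antiviral gene Mx1 (0.86) past the threshold in the authors' deposited table and 15 members past it when adjusted over the list alone. None of the interferon genes was called with the F distribution. The 10 MHC class II genes rose as a list (median 0.49, cameraPR adjusted p = 1.35e-06), with none past the threshold over all genes and 7 past it when adjusted over the list alone or at an unadjusted p under 0.05. Neutrophil markers (11 measured, median 0.30, cameraPR adjusted p = 0.0887) and general chemokine and inflammation genes (21 measured, median 0.20, cameraPR adjusted p = 0.323) did not pass as lists, though neutrophil markers did with ranks (cameraPR adjusted p = 0.0495). No neutrophil marker passed over all genes or over the list alone, and 2 had an unadjusted p under 0.05 in edgeR's test. Among the chemokine and inflammation genes the stromal chemokine gene Cxcl12 fell by 0.82 on the log2 scale (adjusted p = 3.14e-05 in the authors' deposited table), the list's 1 call over all genes and over the list alone.

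**Figure D2:**
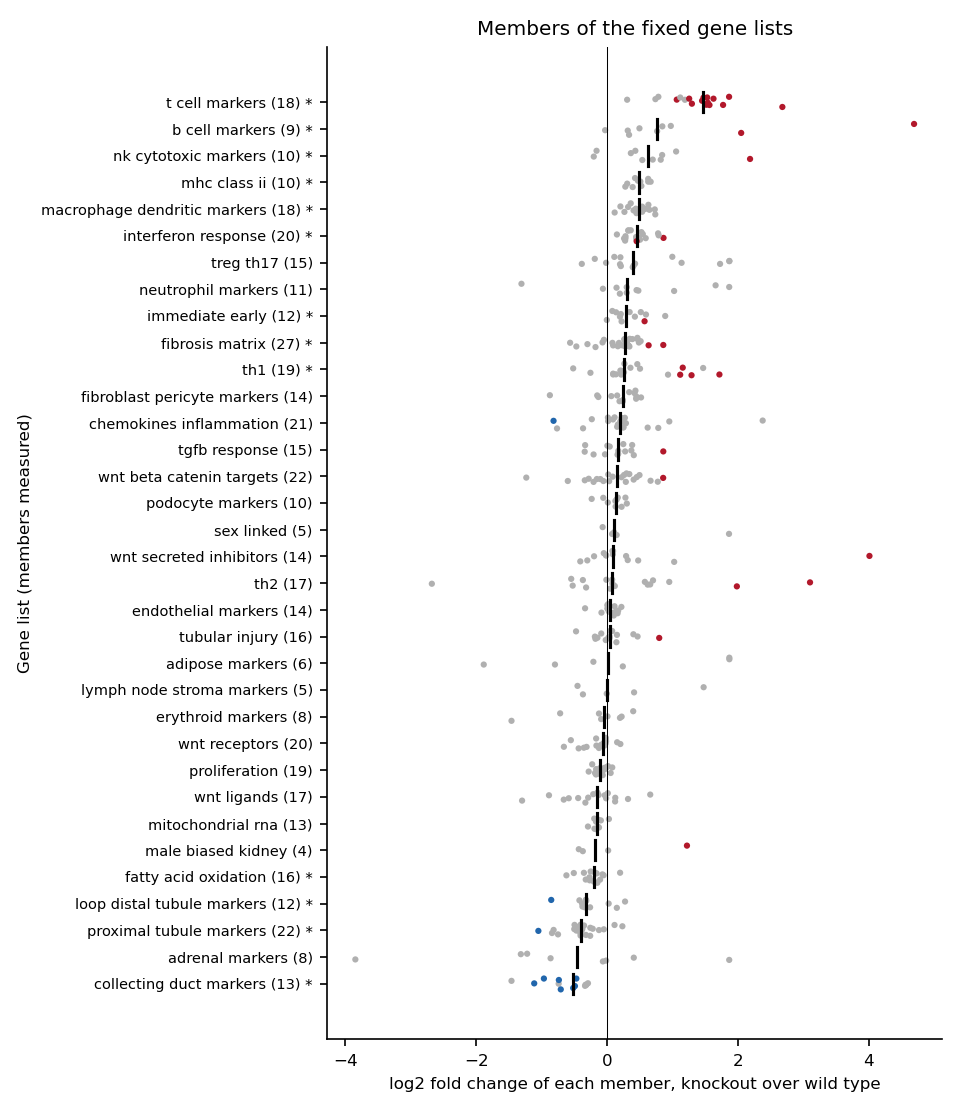
Log2 fold change of each measured member (points, horizontal axis) of the 34 gene lists fixed before the data were examined, with the number measured in parentheses and the list median as a black bar. Red and blue members passed an adjusted p of 0.05 upward and downward, and an asterisk marks the 13 lists past an adjusted p of 0.05 in cameraPR, from T cell markers (median 1.46) to collecting duct markers (median -0.52).

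Genes of the renal tubule fell, with the lowest list median in the collecting duct, the segment that sets final water, salt and acid excretion. All 13 collecting duct markers were below 0 with a median of -0.52, or 1.43-fold (cameraPR adjusted p = 1.15e-18). Of these 7 were called over all genes and 13 when adjusted over the list alone. In the authors' deposited table the chloride and bicarbonate exchanger gene Slc26a4 (chromosome 12, 31519827 to 31559969) fell by 1.11 on the log2 scale (adjusted p = 5.08e-07), the water channel gene Aqp3 by 0.97 (adjusted p = 1.62e-04), the proton pump subunit gene Atp6v1b1 by 0.71 (adjusted p = 0.00103) and the sodium channel subunit gene Scnn1g by 0.49 (adjusted p = 0.00491). With the F distribution 2 of the 13 still passed. On chromosome 7 lie 2 of the 13, among them Scnn1g. Without that chromosome 5 of 11 were called, and the list still fell (cameraPR adjusted p = 4.65e-18). Loop and distal tubule markers fell as a list (12 measured, median -0.32, cameraPR adjusted p = 4.45e-04), with 1 called, the calcium-binding protein gene Calb1 (-0.85, adjusted p = 0.0277 in the authors' deposited table), and 3 when adjusted over the list alone. Proximal tubule markers fell as a list (22 measured, median -0.40, cameraPR adjusted p = 2.72e-06), with 1 called, the gluconeogenic enzyme gene Pck1 (-1.05, adjusted p = 0.0224 in the authors' deposited table), and 2 when adjusted over the list alone. Neither Calb1 nor Pck1 was called with the F distribution. Fatty acid oxidation genes, a main energy pathway of the proximal tubule, fell as a list (16 measured, median -0.20, cameraPR adjusted p = 6.96e-04) with none called over all genes or over the list alone and 2 at an unadjusted p under 0.05 in edgeR's test.

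Glomerular and vascular markers did not pass. The median log2 fold change was 0.14 for 10 podocyte markers (cameraPR adjusted p = 0.219) and 0.04 for 14 endothelial markers (cameraPR adjusted p = 0.651), with no member of either at an unadjusted p under 0.05 in edgeR's test and none past the threshold over the list alone. Mitochondrially encoded transcripts (13 measured, median -0.15, cameraPR adjusted p = 0.0887) and proliferation genes (19 measured, median -0.11, cameraPR adjusted p = 0.0887) did not pass either, with no member at an unadjusted p under 0.05 in edgeR's test. With ranks both passed as falling lists (cameraPR adjusted p = 0.00778 and 0.0111).

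Fibrosis genes rose as a list by a small amount. The 27 matrix genes had a median log2 fold change of 0.27, or 1.21-fold (cameraPR adjusted p = 8.77e-04). Of these, 2 were called, also the number adjusted over the list alone, among them the protease inhibitor gene Timp1 (0.64, adjusted p = 0.0215 in the authors' deposited table), while the collagen gene Col1a1 stood at 0.32 (adjusted p = 0.609). No matrix gene was called with the F distribution. Of 15 TGF-beta response genes 1 was called over all genes and over the list alone, and they did not pass as a list (median 0.17, cameraPR adjusted p = 0.0593). The 14 fibroblast and pericyte markers did not pass either (median 0.24, cameraPR adjusted p = 0.0607), but they did without chromosome 7 (cameraPR adjusted p = 0.0420) and with ranks (cameraPR adjusted p = 0.0280). None of these was called over all genes or over the list alone, and 4 had an unadjusted p under 0.05 in edgeR's test. Tubular injury genes did not pass as a list (16 measured, median 0.04, cameraPR adjusted p = 0.294). The cell cycle inhibitor gene Cdkn1a (chromosome 17, 29090976 to 29100727) was the 1 member that rose, over all genes and over the list alone, by 0.80 on the log2 scale (adjusted p = 4.18e-09 in the authors' deposited table). The injury marker gene Havcr1 had a log2 fold change of 0.40 (adjusted p = 0.353) in the authors' deposited table. Immediate early genes rose as a list (12 measured, median 0.28, cameraPR adjusted p = 4.45e-04), with Egr1 called (0.57, adjusted p = 0.0216 in the authors' deposited table) and 2 members past the threshold over the list alone. No TGF-beta response or immediate early gene was called with the F distribution.

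Wnt pathway lists did not pass in the main setting. The median log2 fold change was -0.15 for 17 Wnt ligands (cameraPR adjusted p = 0.0790) and -0.06 for 20 receptors and co-factors (cameraPR adjusted p = 0.191), with none called over all genes or over the list alone and 4 and 1 members at an unadjusted p under 0.05 in edgeR's test. With ranks both passed narrowly as falling lists (cameraPR adjusted p = 0.0495 for each). The median was 0.09 for 14 secreted inhibitors (cameraPR adjusted p = 0.280) and 0.15 for 22 beta-catenin targets (cameraPR adjusted p = 0.280). The called members in the authors' deposited table were the inhibitor family gene Dkkl1 (4.01, adjusted p = 0.00142), at an average of 0.338 CPM and on chromosome 7 with Dkk3, and Tcf7 (0.86, adjusted p = 0.0471), a transcription factor gene that T cells also express. Neither was called with the F distribution, and the Tcf7 call also ended without chromosome 7, with the inflation factor and after centring. Over the list alone 1 inhibitor and 4 targets passed, 2 targets higher and 2 lower.

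The authors' own pathway sheets held 1 to 5 genes past the threshold each. Of all genes in the authors' deposited table, 2.06% passed, a lower share than in any of the 3 sheets, which was not tested. How the members were chosen is not known, so the sheets are not independent evidence of a direction. In the authors' deposited table, 5 of 74 Wnt-related genes passed, Dkkl1, Gbp7 (0.41), the stromelysin gene Mmp3 (1.06) and Tcf7 upward and the keratin gene Krt4 (-2.55, at an average of 0.473 CPM) downward, and the sheet did not move as a list (median -0.04, cameraPR adjusted p = 0.897). Over that sheet alone 7 higher and 4 lower genes passed. Of 20 Th1-related genes 1 passed in the authors' deposited table, Cxcr3, 2 passed over the sheet alone, and the sheet rose as a list (median 0.45, cameraPR adjusted p = 0.00281). Of 15 Th2-related genes 2 passed in the authors' deposited table and over the sheet alone, the chemokine receptor gene Cxcr6 (1.18) and Mical2 (0.86), and the sheet did not move as a list (median -0.07, cameraPR adjusted p = 0.897). Mical2 begins 66.8 kb from Dkk3 on chromosome 7. The transcription factor gene Gata3 of the Th2 sheet had a log2 fold change of -0.37 (adjusted p = 0.262) in the authors' deposited table.

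The authors' over-representation test of 9062 Gene Ontology terms put immune terms on the rising side and membrane transport terms on the falling side. For rising genes 168 terms passed an adjusted p of 0.05 in the authors' deposited table, led by immune system process (65 rising of 1493 genes, adjusted p = 1.95e-17), lymphocyte activation (32 of 470, adjusted p = 3.75e-12) and T cell activation (27 of 333, adjusted p = 7.73e-12). For falling genes 41 terms passed in the authors' deposited table, led by plasma membrane region (20 falling of 361 genes, adjusted p = 9.77e-07), apical plasma membrane (15 of 231, adjusted p = 1.41e-05), membrane region (23 of 620, adjusted p = 2.99e-05) and monovalent inorganic cation homeostasis (9 of 73, adjusted p = 4.51e-05), with water homeostasis also past it (5 of 23, adjusted p = 0.00173).

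Genes on the chromosome of Dkk3 were called more often than others. Leaving out Dkk3 itself, 20 of 177 genes within 10 Mb of it were called, or 11.3%, against 355 of 18136 other genes. The odds ratio was 6.38 (95% interval 3.75 to 10.3, two-sided Fisher's exact p = 6.65e-10). Within 5 Mb 4 of 62 were called, with an odds ratio of 3.32 and a 95% interval of 0.872 to 9.05 that includes 1. Over the whole of chromosome 7, 102 of 1416 genes other than Dkk3 were called, or 7.20%, 44 higher and 58 lower. On other chromosomes 273 of 16897 were called, or 1.62% (odds ratio 4.73, 95% interval 3.70 to 6.00, two-sided Fisher's exact p = 1.74e-30). The other 19 chromosomes with at least 100 tested genes lay between 0.881% and 2.48%. By 5 Mb bins the share was 17.2% at 40 to 45 Mb, 21.6% at 45 to 50 Mb, 25% at 60 to 65 Mb (4 of 16 genes), 18.7% at 100 to 105 Mb, 6.06% at 110 to 115 Mb, the bin of Dkk3, and 0.926% at 140 to 145 Mb. The bins count Dkk3 itself, which was 1 of the 2 calls among the 33 genes of its bin. None of the 61 genes in the bin from 0 to 5 Mb was called in edgeR's test. Trim12a (104299894 to 104315466), Htatip2 (49759115 to 49773975), Ftl1 (45457944 to 45459884) and Gas2 (51862015 to 51994975) all lie on chromosome 7, as do 15 of the 20 genes with the smallest p in the authors' deposited table. Leaving chromosome 7 out, 242 genes passed, 151 higher and 91 lower, 62.4% of them higher against 56.7% in the whole table.

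**Figure D3:**
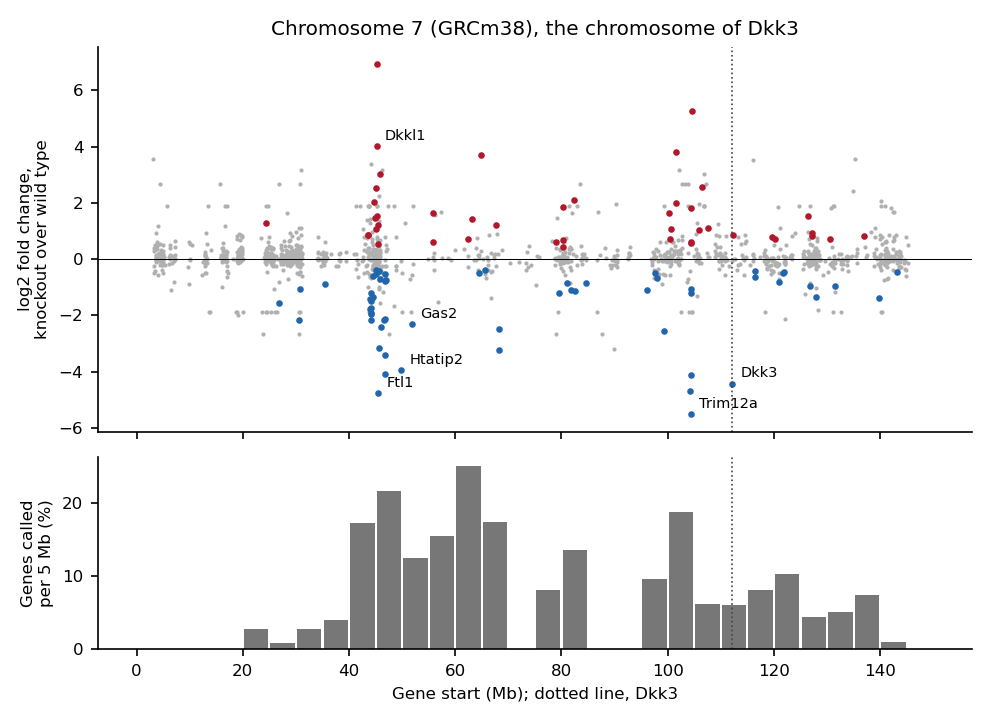
Upper panel, log2 fold change (knockout over wild type) of each tested gene on chromosome 7 against its start in Mb on GRCm38, with genes called higher in red and lower in blue. Lower panel, percentage of tested genes called in each 5 Mb bin, Dkk3 included, such as 21.6% at 45 to 50 Mb and 25% at 60 to 65 Mb (4 of 16 genes). Of the 102 calls other than Dkk3, 66 lay more than 20 Mb from it (dotted line).

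Markers of other tissues and of sex were measured alongside. Erythroid (8 measured, median -0.04, cameraPR adjusted p = 0.293), adipose (6, median 0.02, adjusted p = 0.760), adrenal (8, median -0.46, adjusted p = 0.129), lymph node stroma (5, median -0.0041, mean 0.21, adjusted p = 0.651) and sex-linked genes (5, median 0.11, adjusted p = 0.280) held no called member in edgeR's test, with 2, 0, 2, 1 and 1 members at an unadjusted p under 0.05. Over the list alone 2 erythroid members, among them Slc4a1, which the collecting duct list also holds, and 1 lymph node member, Cxcr5, passed. Of 4 male-biased kidney genes Cyp4a12a rose (1.22, adjusted p = 0.00410 in the authors' deposited table), 1 higher and 1 lower member passed over the list alone, and the list did not pass (median -0.18, mean 0.11, cameraPR adjusted p = 0.887). Cyp4a12a was not called with the F distribution.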

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

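No paired analysis was possible because the table holds no value per sample, and for the same reason leaving out single mice, other normalizations, DESeq2, voom, the exact test, robust dispersion, a filter on counts, fry, an estimated correlation and other splits of the 6 samples (10 of equal size) were not run; depth per sample is unknown, so what depth limits could not be judged. Settings other than a threshold of 0.1, a fold change of at least 1.5, an average of at least 1 CPM and the windows were chosen after seeing the data. Dkk3 stayed negative and past the threshold in each setting run, with adjusted p between 1.48e-67 and 2.38e-07. The 379 changed genes became 578 at an adjusted p of 0.1, by construction, and 81 with the F distribution, which has wider tails. Without chromosome 7 the number was 242, below the 273 called on other chromosomes in the main setting. Some calls elsewhere thus depended on being adjusted together with the small p of chromosome 7. The other settings gave 287 to 379. Of the authors' sheets, the Wnt count of 5 was 2 without chromosome 7, 1 with the statistics divided by their inflation factor and 0 with the F distribution, the Th1 count of 1 was 2 at an adjusted p of 0.1 and 0 with the F distribution, and the Th2 count of 2 was 1 without chromosome 7 and 0 with the F distribution. The number of lists past 0.05, 13 of 34, was 13 to 15 in the other settings and 20 with ranks, each holding the same 13; the Th2 list was gained at 1 CPM or more, it and fibroblast and pericyte markers without chromosome 7, and with ranks the latter, Wnt ligands, Wnt receptors, proliferation, mitochondrial, neutrophil and regulatory T and Th17 genes; the cause was not tested. With the F distribution the called Th1, fibrosis and interferon genes went from 4, 2 and 2 to 0. Near Dkk3 the odds ratio was 6.38 at 10 Mb, 3.32 at 5 Mb (Fisher's exact p = 0.0381, with a 95% interval of 0.872 to 9.05 that includes 1) and 4.91 at 20 Mb. The 209 Gene Ontology results past the threshold (168 rising and 41 falling, 1 term in both) became 123 at an adjusted p of 0.01, by construction. Among named genes, 28 lost their call with the F distribution, 8 with the inflation factor, 4 with the fold change minimum, 3 without chromosome 7 and 1 after centring, while 11 gained one at an adjusted p of 0.1 and 2 at 1 CPM or more, and no called gene turned direction.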

Other observations

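The tests of this part were chosen after the results were seen, but those on urothelial genes, p53 targets and genes shared by tubule segments ran on genes not looked at before. Genes of the urothelium, the lining of the renal pelvis and ureter, were lower in the knockout, a group outside the comparisons above. Of 9 uroplakin and stratified keratin genes chosen after their values were seen, 9 were below 0, with a median log2 fold change of -2.16, and 4 were called, Upk1a, Upk3a, Upk3b and Krt4, against 3 with the inflation factor, 2 without chromosome 7 and 0 with the F distribution. Because those genes were picked for their fall, a second list of urothelial genes not looked at before was set up, and the hypothesis that the knockout samples held less urothelium was tested on it. All 9 measured genes of it were below 0, with a median of -1.37, among them Psca (-1.37), Foxa1 (-1.54) and Dsg3 (-1.87), and it fell as a list (cameraPR on the authors' statistics, p = 1.60e-06). None of the 9 was called over all genes in edgeR's test, 4 passed over the list alone and 5 had an unadjusted p under 0.05. This is consistent with less urothelial RNA, while how much renal pelvis was taken with each kidney is not known.

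Among the rising genes were the p53 transcription factor targets Cdkn1a, Eda2r, Psrc1, Phlda3, Aen, Ephx1 and Sesn2, 7 called of 10 picked after their values were seen and 4 with the F distribution, which by itself shows no excess of such targets. A hypothesis that p53 targets rose as a class was tested on 18 targets not looked at before. None was called in edgeR's test, 4 had an unadjusted p under 0.05, the median log2 fold change was 0.10, and the list passed narrowly (cameraPR on the authors' statistics, p = 0.0390). It no longer passed with a preset correlation of 0.05 (cameraPR on the authors' statistics, p = 0.101), so a rise of the class may be small and rests on that setting.

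The called genes concentrated on chromosome 7. A local effect of the deletion on its neighbours does not account for it, since beyond 20 Mb from Dkk3 the odds ratio against other chromosomes was still 4.30 (95% interval 3.21 to 5.70). That excess lay on the side before Dkk3, where the ratio was 4.91 (95% interval 3.64 to 6.55), while on the side after it 3 of 156 genes were called and no excess was seen (1.19, 95% interval 0.242 to 3.59). Families of related genes lying side by side do not either, since counted once per 1 Mb bin, 45 of 125 bins with tested genes held a call against 224 of 2051 elsewhere (odds ratio 4.58, 95% interval 3.03 to 6.88). A donor-strain interval carried along with the deleted allele can be short or long, so it allows an excess far from the gene but does not require one. The ratios of 4.30 in all and 4.91 before the gene are allowed by such an interval and do not single it out. The share of calls was not highest at the gene, which alone does not argue for or against such an interval. It was 6.06% at 110 to 115 Mb, where Dkk3 itself was 1 of 2 calls, against 21.6% at 45 to 50 Mb. No gene was called in the bins from 0 to 20 Mb, and 0.787% to 4% were per bin from 20 to 40 Mb. From 40 to 140 Mb the bins ranged from 0% to 25%, and the bin at 140 to 145 Mb held 0.926%. The genotypes were not analysed here, and strain variants that change transcript levels and those that change how reads align could not be separated. The sheet genes and named genes on this chromosome include Dkkl1, Mical2, Scnn1g, Ftl1, Trim12a, Htatip2, Gas2, Upk1a and the kallikreins. Hddc3, Tead2, Cpt1c, Itgax and Cd22 lie there too.

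T cell markers rose together. Fewer tubule cells would raise every other cell type alike, whereas the mean of T cell markers exceeded that of endothelial and podocyte markers by 1.31 on the log2 scale (1.38 against 0.07, permutation p = 1e-05, the smallest that 100000 permutations can give). Lymph node tissue taken with the kidney would bring mature B cell and follicle genes, whose mean was lower by 0.98 (0.40, permutation p = 2e-05). That comparison cannot exclude such tissue, because its B cell genes were chosen after the values were seen and left out the risen Igj and Mzb1. The whole B cell list had a mean of 1.16. Of the 5 lymph node markers 2 were above 0, among them Cxcr5 at 1.48, and 3 below. On chromosome 7 lie 3 of the 7 mature B cell genes. Their list, which rose narrowly (cameraPR p = 0.0322), did not pass without them (cameraPR p = 0.438) or with a preset correlation of 0.05 (cameraPR p = 0.0531). The rise does not rest on markers that lie on chromosome 7, which holds 1 of the 18. Without that chromosome the list had a cameraPR adjusted p of 2.39e-28. Whether genes of chromosome 7 act on T cells was not tested. A larger number of T cells in the knockout kidney stays open as a hypothesis that cell counts would have to test.

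Collecting duct markers fell together. Fewer tubule cells of every kind was examined with 8 genes shared by tubule segments. Their mean of -0.12 lay above the -0.65 of collecting duct markers by 0.53 (permutation p = 5.3e-04). It also lay above the -0.39 of proximal tubule markers and the -0.26 of loop and distal tubule markers. The shared genes may thus not follow the number of tubule cells, and the comparison cannot decide the question. They too were lower as a list (cameraPR p = 0.0380), which no longer passed with a preset correlation of 0.05 (cameraPR p = 0.0647). Less medulla in the tissue taken is argued against as the whole cause, because proximal tubule markers of the cortex fell as well (cameraPR on the authors' statistics, p = 5.60e-07). The fall of urothelial genes (median -1.37 in the list not looked at before) could go with less inner tissue as a part of the cause. Fewer tubule cells of every kind stays open. So do a mixture of that with less medulla, a loss of collecting duct cells, and lower expression per cell, which were not tested.

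Neighbouring genes of the Cyp4a family on chromosome 4 went in opposite directions, with Cyp4a12a at 1.22 and Cyp4a14 at -3.14 on the log2 scale in the authors' deposited table. The nicotinamide nucleotide transhydrogenase gene Nnt, which differs between C57BL/6 substrains, had a log2 fold change of -0.11 (adjusted p = 0.896 in the authors' deposited table).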
